A study of Mus musculus with 8 samples.

How the data were processed

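Liver RNA of 8 male mouse samples was measured by RNA sequencing, 4 from db/db mice and 4 from lean mice. The db/db mouse carries a mutated leptin receptor gene (Lepr) and becomes obese and diabetic. Per the labels' protocols, total RNA was taken with TRIzol, ribosomal RNA was removed and stranded total RNA libraries were made. The strain label of the lean samples is C57BL/6, while that of the other group is only db/db, so the background strain of the db/db mice is not given in the sources used here. Samples were grouped and numbered by their titles. The labels describe separate samples without naming the animal behind each, so p-values measure the spread between these samples, which may in part be technical.

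Per the submitters' processing notes, cutadapt 1.9.3, HISAT2 2.0.4, Cufflinks and Cuffdiff were used with the mouse build mm10, with no role or order given. The deposited table held 22564 rows with values, all protein coding, and 1 further row was empty and not analysed here. It gave 2 measures per sample. The first was FPKM (fragments per kilobase of transcript, scaled to the fragments of the library), per the file headers, computed by the authors with a transcript length that is not given in the sources used here. The second was headed counts, but its values were a normalized signal: the deposited values were estimated fragments per gene divided by a size factor of each library. Of values below 2000 steps, 91.3 to 92.0% were whole multiples of 1 step per library, within 0.05 of a step, with steps from 0.850 to 1.14. The remaining values were fractional, some close to 0, so the main test used FPKM. Dividing by the step gave the estimated fragments, used for depth, to compare replicates and in voom.

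Exact zeros in the table, and values above 0 that amount to far less than 1 fragment, need care. Alb, the gene of serum albumin and one of the most abundant liver transcripts, was listed at 0 in all 8 samples, and several mitochondrial genes were listed at 0 in db/db samples. Such genes are given as values, with no fold change. Of the 22564 rows, 5877 shared a locus with another row, so overlapping genes are uncertain, as are members of families of near-identical genes (Mup, Serpina1, Sult2a, Cyp2b, Cyp4a and Cyp3a41). Of the 82 genes named by the rule below, 17 shared a locus: Mettl3, mt-Nd4, Hsd3b5, Psmd1, Mogat1, Pcx, Pklr, Igfbp2, Orm2, Dbp, Ccnd1, Mcm2, Rhbg, Slc1a4, Folr2, Clec4g and Spp1.

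Rows of the same symbol were summed, which affected 162 rows of 79 symbols and gave 22481 genes. Genes entered the test when FPKM was at least 0.5 in at least 4 of the 8 samples, which left 10943. The values log2(FPKM + 1) were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 fold changes are db/db minus lean. They are on the log2(FPKM + 1) scale, which understates the change of low genes, except those given with voom, which are on estimated fragments. Folds are ratios of mean FPKM. Every adjusted p is from limma unless another test is named.

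Gene lists, 31 in all and 10 of them cell type markers, were fixed before the data were examined, together with the design and most alternatives. The 27 lists with at least 3 tested members, leaving out the list of study genes, were tested with camera of limma at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. For each list, the number of members past the threshold is given over all genes tested and adjusted over the list alone. Named genes followed a rule: the study genes and Lepr, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap, and for each list the 2 called members with the smallest adjusted p and the member with the highest mean. A list member named because it went against its list, and every gene named in the closing part outside these 82, was chosen after the values were seen. A few genes that the rule or their list would name are not reported here. They stay in the counts of their lists and were left out of the outlier count after it had been made.

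On simulated values with the means and spread of the 10943 genes, limma recovered 22.4% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 98.5% of those changed by 2, with 5 false calls. Voom, on fragments simulated with the same dispersion for every gene, recovered 2.99%, 61.2% and 100% of the same sizes of change with 3 false calls. The noise of the simulations differed, so these rates do not compare the power of limma and voom. Small changes were often missed in both. Camera found 5 of 5 changed lists and 0 of 20 unchanged ones, for simulated genes that varied independently of each other, which real genes do not.

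The alternatives were other pseudocounts, no filter and a stricter one, median-ratio rescaling, quantile normalization, robust eBayes, library weights, a replicate block, each sample left out in turn and each row as its own gene. Chosen after seeing the data were limma voom on the estimated fragments, leaving out mitochondrial genes, and leaving out genes that share a locus. Gene positions come from the GENCODE M21 annotation of the same build, matched by Ensembl ID for 21839 of the 22564 rows, of which 21813 overlapped the table's own locus. No pair of replicates was the same library sequenced again: the chi-square per gene between replicates of 1 group was 13.2 to 80.2, where counting noise alone gives about 1. Repeat libraries of the same animal are not excluded by this. Python 3 with pandas and matplotlib read the table and drew the figures.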

Results

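The data set compared the liver transcriptome of obese, diabetic db/db mice with that of lean mice, in a study of nonalcoholic fatty liver disease and RPN11, a deubiquitylating enzyme of the proteasome encoded by Psmd14. Each group held 4 male samples. Estimated fragments in protein-coding genes numbered 16171667, 13975643, 13157732 and 14348937 in db/db samples 1 to 4, and 14978548, 12174820, 13064783 and 12948652 in lean samples 1 to 4. At this depth 13633 to 14050 genes per sample had at least 1 estimated fragment. The 10 genes with the most fragments took 12.0 to 14.8% of fragments in db/db samples and 15.3 to 16.2% in lean samples. These shares depend on genes listed at 0. The mitochondrial gene mt-Co1 had 227360 to 279940 estimated fragments in lean samples and 0 in every db/db sample. Alb was at 0 in every sample. The gap between the groups may thus come in part from such zeros, and shares without these genes were not computed.

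The db/db livers had higher levels of many genes of fatty acid synthesis, lipid storage and fatty acid oxidation, and of genes usually higher in female than in male liver. Of genes usually higher in male liver 8 of 12 were lower, as were 6 of 21 genes of cholesterol synthesis and 4 of 11 Kupffer cell markers. Of 10943 genes tested, 2892 differed between the groups by limma, 1694 higher and 1198 lower in db/db, and 637 of them differed at least 2-fold, a count that depended on the pseudocount and the measure (1011 with a pseudocount of 0.1 and 1045 with voom). The first principal component held 63.4% of the variance and separated the groups. The second, with 10.7%, set db/db 1 (score 29.6) apart from the other db/db samples (at most -4.59). Without db/db 1, 2498 genes differed. Correlations of log2 values across genes, which are not independent replicates, were 0.975 to 0.989 within db/db, 0.980 to 0.988 within lean and 0.932 to 0.951 between the groups.

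The first question, from the study's title, was how Psmd14 itself differed. Psmd14 (ENSMUSG00000026914, chromosome 2, 61711694 to 61800376, plus strand) was 1.48-fold higher in db/db, at 44.5 ± 6.95 FPKM against 30.1 ± 4.40 (SD, n = 4 each; log2 fold change 0.55, SE 0.14, limma adjusted p = 0.0171). Acss3 (ENSMUSG00000035948, chromosome 10, 106933517 to 107123668, minus strand), which encodes a mitochondrial enzyme that activates short-chain fatty acids, rose from 0.517 ± 0.306 to 13.3 ± 4.38 FPKM (log2 fold change 3.21, SE 0.22, limma adjusted p = 4.7e-06). Mettl3 (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128, minus strand), the catalytic subunit of the m6A RNA methyltransferase, was 1.62-fold lower, at 6.85 ± 1.02 against 11.1 ± 1.31 FPKM (log2 fold change -0.63, SE 0.13, limma adjusted p = 0.00545). In each of these 3 genes every db/db sample lay on one side of every lean sample in FPKM, and an exact 2-sided permutation test gave p = 0.0286, the smallest possible with 4 against 4.

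All 3 study genes were also called when adjusted over the list alone, but Acss3 and Mettl3 are known from the study, which may have picked them on these samples, so this is not independent evidence. The Psmd14 call was lost without db/db 2 (limma adjusted p = 0.0534) and without db/db 4 (limma adjusted p = 0.0520). The Mettl3 call was lost with voom on estimated fragments, an alternative chosen after seeing the data (log2 fold change -0.29, adjusted p = 0.153, against 0.00374 to 0.153 over all alternatives). Relative to library depth, estimated fragments of Mettl3 overlapped between the groups (CPM 9.42 to 11.8 in db/db and 11.6 to 14.3 in lean). The Mettl3 locus is shared by 3 rows of the deposited values, so its level is uncertain. Lepr was low in both groups, at 0.617 ± 0.0879 FPKM in db/db and 0.719 ± 0.205 in lean (log2 fold change -0.08, limma adjusted p = 0.652). With voom it was called lower (log2 fold change -1.48, adjusted p = 0.0223), on 11 to 34 estimated fragments per db/db sample and 28 to 82 per lean sample. The db mutation alters splicing of the long receptor form, so this gene-level value does not check the genotype.

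**Figure D1:**
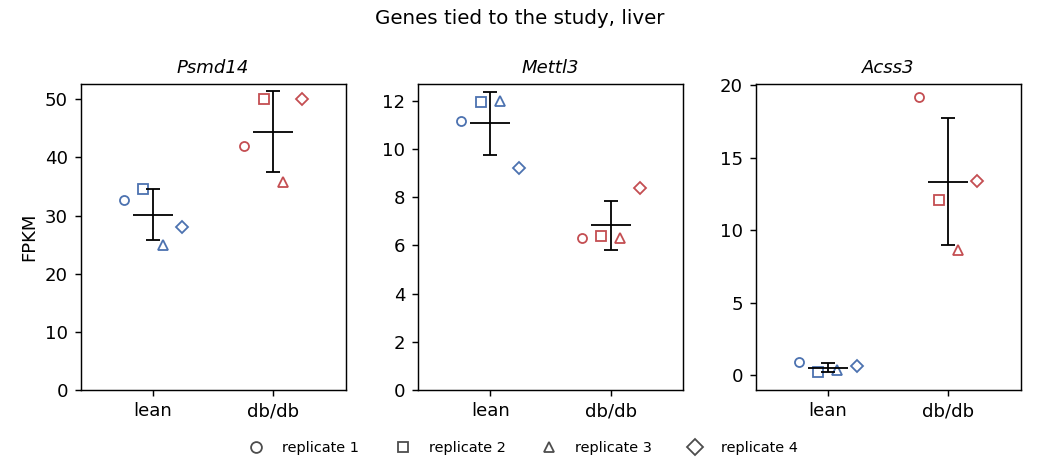
FPKM (vertical axes, linear) of Psmd14, Mettl3 and Acss3 in lean and db/db liver, with 1 symbol per sample, and a horizontal bar and whiskers for the mean and SD of 4 samples. Psmd14 averaged 44.5 in db/db against 30.1 in lean, Mettl3 6.85 against 11.1 and Acss3 13.3 against 0.517.

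Few other proteasome genes were called along with Psmd14. Of 32 proteasome subunits tested, 3 rose, Psmd14 itself among them, and 1 fell, over all genes and adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.473). Since limma recovered 22.4% of simulated changes of 0.5, subunits without a call may have changed as much as Psmd14. Psmd1, the largest subunit of the regulatory particle, rose from 27.7 ± 3.62 to 40.9 ± 2.96 FPKM (log2 fold change 0.55, limma adjusted p = 0.00598). Psmb6, a catalytic subunit of the core particle, fell from 230.7 ± 27.4 to 172.6 ± 10.2 FPKM (log2 fold change -0.41, limma adjusted p = 0.0178), a call lost without lean 1 (adjusted p = 0.0550). Of 14 writers, erasers and readers of m6A tested, 1 rose and 3 fell by both adjustments, without a call for the list (camera adjusted p = 0.446). Igf2bp2, an m6A reader, rose from 0.144 ± 0.0426 to 0.860 ± 0.278 FPKM (limma adjusted p = 0.00257), and Ythdc1, a nuclear reader, fell from 15.4 ± 0.983 to 10.7 ± 2.98 FPKM (limma adjusted p = 0.0482). The Ythdc1 call was kept in 10 of 21 alternatives. It was lost with voom (adjusted p = 0.525), without db/db 1 or 3 and without any 1 lean sample (adjusted p = 0.0610 to 0.101). A replicate block, library weights, no filter and a pseudocount of 0.1 also ended it (limma adjusted p = 0.0663, 0.07125, 0.0877 and 0.0512).

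Genes that make fatty acids and triglycerides rose in db/db liver. Of 18 tested, 12 rose and 1 fell, or 13 and 1 adjusted over the list alone. Scd1, the desaturase that makes monounsaturated fatty acids, rose 8.25-fold to 3458 ± 1202 FPKM (SE of the log2 fold change 0.29, limma adjusted p = 4.27e-05). Elovl6, a fatty acid elongase, rose 8.68-fold from 6.56 ± 3.48 to 57.0 ± 12.1 FPKM, and Gpam, which starts glycerolipid synthesis, rose 5.51-fold from 4.33 ± 1.54 to 23.9 ± 3.29 FPKM (limma adjusted p = 3e-05 and 3.22e-05). The member that fell was Lpin1, a phosphatidate phosphatase (log2 fold change -2.42). The list was called by camera (adjusted p = 0.000158), with adjusted p = 0.415 with an estimated correlation.

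Lipid droplet and fatty acid uptake genes followed the same direction, with 13 of 18 higher and 0 lower, or 13 and 1 adjusted over the list alone. Cd36, a fatty acid transporter (chromosome 5, 17781690 to 17888801, minus strand), rose 21.9-fold from 4.72 ± 1.74 to 103.5 ± 5.18 FPKM (log2 fold change 4.25, SE 0.20, limma adjusted p = 3.51e-07). Mogat1, a monoacylglycerol acyltransferase, rose from 0.567 ± 0.367 to 13.3 ± 5.78 FPKM. Plin2, a coat protein of lipid droplets, rose from 165.4 ± 56.5 to 336.6 ± 101.9 FPKM (limma adjusted p = 0.0263), a call that leaving out db/db 2, 3 or 4 or lean 3 ended (adjusted p = 0.0591 to 0.0682). The list was called by camera (adjusted p = 1.28e-05), with adjusted p = 0.415 with an estimated correlation.

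Fatty acid oxidation and ketogenesis genes rose as well, with 17 of 24 higher and 0 lower by both adjustments. Cyp4a14 and Cyp4a10, omega-hydroxylases of fatty acids and close paralogs whose reads can be shared, rose 22.8-fold to 854.3 ± 192.2 FPKM and 10.6-fold to 1051 ± 260.9 FPKM (limma adjusted p = 2.55e-05 and 3.72e-06). Camera called the list (adjusted p = 2.65e-07), with adjusted p = 0.415 with an estimated correlation. Of 12 genes of short-chain acyl-CoA and propionate metabolism, 5 rose and 1 fell, or 9 and 1 adjusted over the list alone. This list holds Acss3, which the study may have chosen on these samples. Hibch, of valine breakdown, rose from 36.3 ± 4.81 to 69.0 ± 3.36 FPKM, and Acsm1, a medium-chain acyl-CoA synthetase, fell 1.46-fold to 155.8 ± 18.6 FPKM (limma adjusted p = 0.000213 and 0.00416). Camera called this list too (adjusted p = 0.00474), with adjusted p = 0.408 with an estimated correlation.

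Genes of cholesterol synthesis that differed mostly fell. Of 21 genes tested, 6 fell and 1 rose by both adjustments. Idi1 and Cyp51, enzymes of the sterol pathway, fell from 67.8 ± 11.9 to 14.6 ± 6.00 FPKM and from 41.6 ± 3.59 to 12.1 ± 1.61 FPKM (log2 fold changes -2.20 and -1.70, limma adjusted p = 0.000101 and 4.91e-06). Sc5d had 182.9 ± 21.5 FPKM in db/db and 154.2 ± 28.8 in lean (limma adjusted p = 0.234). The list was called by camera (adjusted p = 0.00642), with adjusted p = 0.536 with an estimated correlation, and not by fry (adjusted p = 0.0564).

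**Figure D2:**
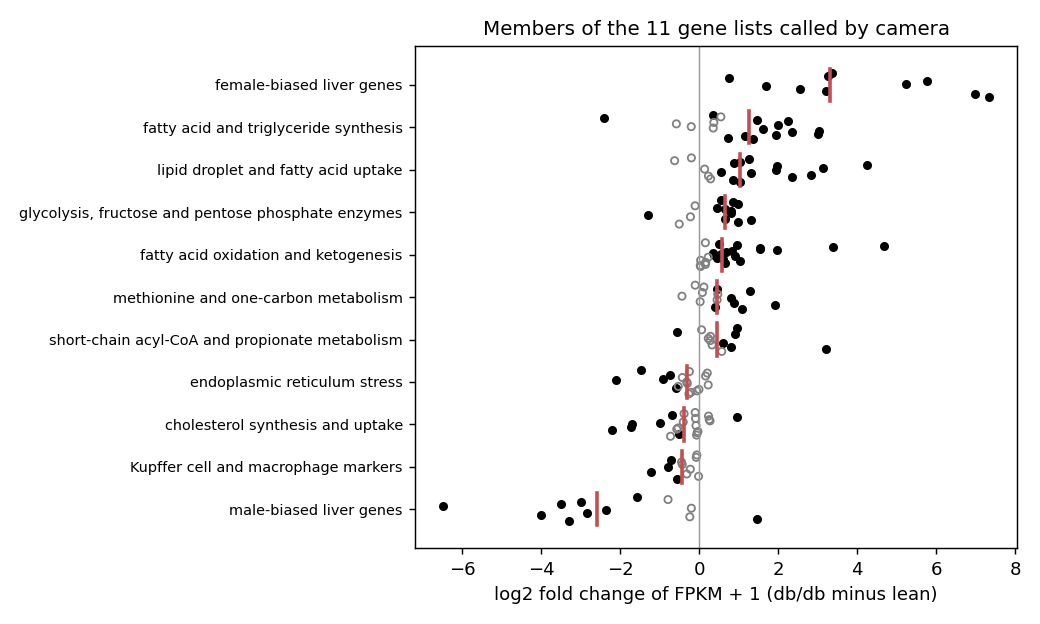
Log2 fold change of FPKM + 1 between db/db and lean liver (horizontal axis) for each tested member of the 11 lists called by camera (vertical axis). Filled points passed the limma threshold, open points did not, and the red line is the median of the list, from 3.31 for female-biased genes to -2.59 for male-biased genes.

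In sugar metabolism, 10 of 14 genes of glycolysis, fructose use and the pentose phosphate pathway rose and 1 fell by both adjustments. Pklr, the liver pyruvate kinase, rose 2.45-fold from 75.5 ± 22.6 to 184.7 ± 33.8 FPKM and Gckr, the regulator of glucokinase, rose 1.99-fold from 27.5 ± 4.73 to 54.7 ± 4.27 FPKM (limma adjusted p = 0.00154 and 0.000484). The member that fell was Pfkfb3, a regulator of glycolytic flux (log2 fold change -1.30). Camera called the list (adjusted p = 0.00642), with adjusted p = 0.415 with an estimated correlation. Of 9 genes of gluconeogenesis and glycogen, 5 rose and 1 fell by both adjustments, with no call by camera (adjusted p = 0.174) and a call as higher by fry (adjusted p = 0.00636). Pcx, pyruvate carboxylase, rose 1.82-fold and Gys2, liver glycogen synthase, fell 2.27-fold (limma adjusted p = 0.000185 and 0.000167). Pck1 had 929.5 ± 100.4 FPKM in db/db and 1099 ± 136.6 in lean (limma adjusted p = 0.195).

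Of 12 genes of insulin and IGF signalling, 1 rose and 3 fell by both adjustments, with no call by camera (adjusted p = 0.123) and a call as lower by fry (adjusted p = 0.00636). Igfbp2, an IGF binding protein, fell 14.7-fold from 667.7 ± 123.9 to 45.3 ± 24.0 FPKM and Igf1 fell from 564.8 ± 40.6 to 376.1 ± 41.4 FPKM (limma adjusted p = 1.54e-05 and 0.00328). Of 14 genes of methionine and one-carbon metabolism, 7 rose and 0 fell, or 8 and 1 adjusted over the list alone. Bhmt, which remethylates homocysteine with betaine, rose 3.81-fold from 1156 ± 133.9 to 4401 ± 597.9 FPKM, and Dmgdh, the next enzyme of betaine breakdown, rose 2.46-fold to 323.8 ± 34.7 FPKM (limma adjusted p = 5.76e-06 and 1.31e-05). Camera called the list (adjusted p = 0.00448), with adjusted p = 0.415 with an estimated correlation.

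Genes that differ between the sexes were among those with the largest changes, although all samples are labelled male. Of 15 female-biased liver genes listed, 10 passed the filter, and all 10 rose by both adjustments. A gene near 0 in lean could pass the filter only if db/db samples expressed it. A rise was thus favoured in advance for such genes, and the share of 10 in 10 is not evidence by itself. Without the filter camera also called the list as higher (adjusted p = 1.86e-06). Cyp2b9, a cytochrome P450 of female liver (chromosome 7, 26173411 to 26210661, plus strand), had 210.8 ± 40.7 FPKM in db/db against 0.324 ± 0.431 in lean (log2 fold change 7.35, SE 0.21, limma adjusted p = 6.32e-09). Cyp2b13, a near relative, had 197.0 ± 127.0 against 0.219 ± 0.301 FPKM. With voom on estimated fragments 6 of the 10 were called. Of 12 male-biased genes, 8 fell and 1 rose, or 9 and 1 adjusted over the list alone. Hsd3b5, a steroid dehydrogenase of male liver, fell from 198.0 ± 31.8 to 1.93 ± 2.79 FPKM, Cyp7b1, an oxysterol hydroxylase, from 208.9 ± 12.98 to 14.8 ± 12.7 FPKM, and Mup3, a major urinary protein, from 15103 ± 701.2 to 3404 ± 2198 FPKM (limma adjusted p = 6.13e-06, 3.39e-05 and 0.000609). Cyp4a12a, of the same Cyp4a family as the oxidation genes, rose (log2 fold change 1.46). Camera called both lists (adjusted p = 2.06e-06 and 2.67e-05), with adjusted p = 0.415 for both with an estimated correlation.

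Sample db/db 1 stood between the groups for several of these genes. Its Sult3a1 level was 0.992 FPKM, against 115.0 to 285.3 in the other db/db samples and at most 0.419 in lean, and its Cyp7b1 level was 33.8 FPKM, against 7.45 to 9.24 in the other db/db samples. Hsd3b5 was at 6.06 FPKM in db/db 1 and at 0.0389 to 1.04 in the others, so this sample makes up most of the db/db mean. Other genes among the 8 with the largest rise were the sulfotransferases Sult2a2, Sult1e1, Sult2a7 and Sult3a1, the P450 gene Cyp2a22 and Ly6d, with log2 fold changes of 5.66 to 7.12. Of these, Sult2a2, Cyp2a22 and Ly6d were also lowest in db/db 1 among the db/db samples. Sult2a7 and Sult1e1 were not, at 278.0 and 131.1 FPKM in db/db 1. The other db/db samples had 234.5 to 337.0 FPKM of Sult2a7 and 123.2 to 234.4 of Sult1e1. The Sult3a1 call was lost with voom (adjusted p = 0.404).

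**Figure D3:**
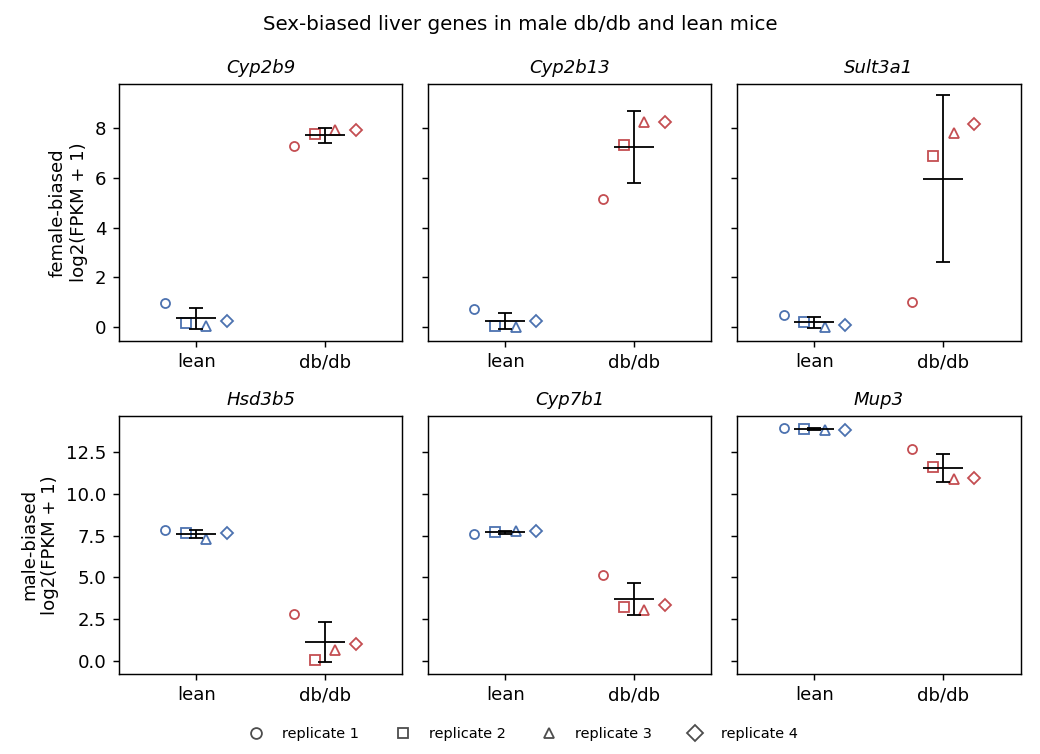
Log2(FPKM + 1) (vertical axes) of the female-biased genes Cyp2b9, Cyp2b13 and Sult3a1 and the male-biased genes Hsd3b5, Cyp7b1 and Mup3 in lean and db/db liver, with 1 symbol per sample, and a bar and whiskers for the mean and SD of 4 samples. The circle of db/db 1 lies nearest to the lean samples among the db/db samples in each panel, for example at 0.992 FPKM of Sult3a1 against 115.0 to 285.3 in the other 3.

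Among the largest falls, mt-Co1, a mitochondrial gene of cytochrome oxidase, was listed at 0 in all 4 db/db samples and at 10029 to 12810 FPKM in lean, and mt-Nd4 was listed at 0 in db/db 1, 2 and 3, at 4493 in db/db 4 and at 4815 to 6929 in lean. No fold is given for genes with such zeros. Rpl21, a ribosomal protein gene (chromosome 5, 146832890 to 146837032, plus strand), fell from 190.5 ± 26.6 to 0.917 ± 0.216 FPKM (log2 fold change -6.64, SE 0.13, limma adjusted p = 2e-10). Serpina1e, an antiprotease of a family of near-identical genes, fell from 8991 ± 1414 to 92.6 ± 63.4 FPKM, and Mup7, another major urinary protein, from 8498 ± 1518 to 213.2 ± 299.8 FPKM, with 661.0 in db/db 1 and 44.1 to 103.1 in the other db/db samples. Selenbp2, a selenium-binding protein, fell 24.6-fold, and Aox3, an aldehyde oxidase, 28.7-fold (limma adjusted p = 1.35e-06 and 3.61e-06).

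Endoplasmic reticulum stress genes were lower where they differed, with 0 of 17 higher and 5 lower by both adjustments. Sdf2l1, an endoplasmic reticulum chaperone partner, fell 4.97-fold from 21.7 ± 5.803 to 4.36 ± 1.66 FPKM and Asns, asparagine synthetase, from 2.59 ± 1.02 to 0.291 ± 0.355 FPKM (limma adjusted p = 0.000185 and 0.00183). Hspa5, the main chaperone, had 311.0 ± 37.6 FPKM in db/db and 375.8 ± 75.1 in lean (limma adjusted p = 0.249). Camera called the list (adjusted p = 0.00448), with adjusted p = 0.415 with an estimated correlation. Of 14 acute phase genes, 3 rose and 3 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.717). Their median log2 fold change was -0.30 and their mean 0.37, so median and mean differ in sign. Lcn2, lipocalin, rose 18.4-fold to 123.2 ± 50.0 FPKM and Orm2, an orosomucoid, 8.71-fold to 247.8 ± 19.3 FPKM (limma adjusted p = 1.46e-05 and 1.43e-07), while Hp, haptoglobin, had 2029 ± 460.0 FPKM in db/db and 2656 ± 497.3 in lean (limma adjusted p = 0.140).

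Of 18 genes of bile acid synthesis and transport, 3 rose and 3 fell by both adjustments (camera adjusted p = 0.720). Abcc4, an export pump, rose from 0.382 ± 0.126 to 2.78 ± 0.996 FPKM (limma adjusted p = 0.000402), and Slc27a5, a bile acid CoA ligase, had 836.9 ± 103.3 FPKM in db/db and 731.5 ± 100.4 in lean (limma adjusted p = 0.303; called higher with voom, log2 fold change 0.50, adjusted p = 0.0173). Of 14 circadian clock genes, 3 rose and 1 fell by both adjustments (camera adjusted p = 0.794), with Nfil3 1.94-fold higher and Dbp 2.62-fold lower (limma adjusted p = 0.00530 and 0.00249). Of 8 cell cycle genes tested, 1 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.777), with Mcm2 at 1.78 ± 0.359 FPKM in db/db against 0.401 ± 0.187 in lean and Ccnd1 at 1.99 ± 0.388 against 5.22 ± 0.444 (limma adjusted p = 0.000645 and 0.000226).

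Of 12 pericentral genes, which mark one zone of the liver lobule, 4 rose and 1 fell, or 5 and 2 adjusted over the list alone. Camera did not call the list (adjusted p = 0.434), and fry called it as higher (adjusted p = 0.0290), although 7 of 12 members were not called and the median log2 fold change was -0.00105. Rhbg, an ammonium transporter, rose 4.27-fold to 19.9 ± 2.36 FPKM (limma adjusted p = 2.06e-05), and Slc1a4, an amino acid transporter, had 0.789 ± 0.0953 FPKM in db/db against 0.130 in lean 2 and values close to 0 in the other lean samples, at a locus that 5 rows share, so its rise is uncertain. Cyp2e1 had 3484 ± 459.2 FPKM in db/db and 4428 ± 441.4 in lean (limma adjusted p = 0.0870; called lower with library weights and without db/db 1, adjusted p = 0.0258 and 0.0358). Of 12 periportal genes, 2 rose and 1 fell by both adjustments (camera adjusted p = 0.779). Aldh1b1, a mitochondrial aldehyde dehydrogenase, rose 1.99-fold and Hsd17b6, a steroid dehydrogenase, fell 3.95-fold (limma adjusted p = 0.000575 and 7.43e-06), while Arg1, arginase, had 1284 ± 111.4 FPKM in db/db and 1245 ± 103.3 in lean (limma adjusted p = 0.803).

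Of the lists of cell type markers, only that of Kupffer cells and macrophages was called by camera in the main test. Of 11 Kupffer cell and macrophage markers, 0 rose and 4 fell, or 6 fell adjusted over the list alone. C1qa, a complement component made by macrophages, fell from 45.1 ± 6.35 to 26.1 ± 4.54 FPKM, Folr2, a folate receptor, from 7.43 ± 2.33 to 4.02 ± 0.522 FPKM and Clec4f, a lectin of Kupffer cells, from 62.7 ± 14.9 to 41.8 ± 6.94 FPKM (limma adjusted p = 0.00313, 0.0129 and 0.0348). The Clec4f call was lost with voom (adjusted p = 0.0648) and without db/db 1, 3 or 4 or lean 1, 2 or 3 (adjusted p = 0.0515 to 0.0865). A replicate block and no filter also ended it (limma adjusted p = 0.0715 and 0.0692). The camera adjusted p was 0.00642, and 0.536 with an estimated correlation, and fry did not call the list (adjusted p = 0.117).

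Of 3 markers of recruited macrophages tested, Cd9 fell (3.91 ± 2.06 against 7.23 ± 1.54 FPKM, limma adjusted p = 0.0390), as it did adjusted over the list alone, a call lost without db/db 1, 3 or 4 or lean 1, 2 or 4 (adjusted p = 0.0738 to 0.105; camera adjusted p for the list = 0.232). Among 10 stellate cell and fibrosis markers, Des fell (limma adjusted p = 0.0325; 0 called adjusted over the list alone; list camera adjusted p = 0.777), a call lost without db/db 2, 3 or 4 or lean 1, 2 or 3 (adjusted p = 0.0573 to 0.0921), and Dcn had 88.1 ± 9.71 FPKM in db/db and 79.4 ± 5.78 in lean (limma adjusted p = 0.360). Clec4g was the 1 endothelial marker of 11 that fell, by both adjustments, from 43.4 ± 3.89 to 30.3 ± 1.87 FPKM (limma adjusted p = 0.00440; camera adjusted p for the list = 0.430). Of 4 cholangiocyte markers, 0 rose and 1 fell, by both adjustments (camera adjusted p for the list = 0.717), with Spp1 at 40.1 ± 8.94 FPKM in db/db and 34.8 ± 8.86 in lean.

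None of 3 neutrophil markers, 5 erythroid markers or the 1 lymphocyte marker tested passed the threshold, by either adjustment (camera adjusted p = 0.136 and 0.248 for the first 2 lists; the third was too short to test). The neutrophil list was called lower with a replicate block (adjusted p = 0.0193), and the lymphocyte and pancreatic acinar lists were called lower without the filter (adjusted p = 0.00679 and 0.0219). S100a9 had 2.79 ± 1.79 FPKM in db/db and 12.5 ± 12.0 in lean, Hbb-bs 204.5 ± 21.5 and 240.9 ± 170.2, and Cd3g 0.369 ± 0.333 and 1.51 ± 1.53 (limma adjusted p = 0.0638, 0.963 and 0.136), and S100a9 was called lower with a replicate block (adjusted p = 0.00491) and without lean 2 (adjusted p = 0.0272). Of 2 adipocyte markers tested, Retn, the hormone resistin, rose from 0.108 ± 0.141 to 5.23 ± 3.01 FPKM, and the 1 pancreatic acinar marker tested, Cela1, an elastase, fell from 17.7 ± 2.88 to 2.30 ± 0.362 FPKM (limma adjusted p = 0.000633 and 1.25e-06), each also when adjusted over the list alone.

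Across the lists, all 11 camera calls were lost with an estimated correlation, and splits of the 8 samples with 2 of each group on each side reached up to 8 called lists, so a list call alone does not exclude chance. Genotype and background strain cannot be separated, since the db/db background is not given.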

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

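Of the tests below, those of mixed lean RNA in db/db 1, of the H2-K1 part alone, of the Rpl21 part alone and of the mitochondrial zeros were chosen after the results were seen. In 164 groups of 4 values, 5 had a sample whose gap to the nearest other was larger, as a share of the group's range, than Dixon's critical value for 4 values, where chance alone gives about 5% of groups. For genes, the gap and the range were taken on the log2(FPKM + 1) scale, while the values shown are FPKM, on which the shares differ. In db/db, Mettl3 was 8.38 FPKM in db/db 4 against 6.32 to 6.38 in the others (gap 0.968 of the range). Cyp7b1 was 33.8 in db/db 1 against 7.45 to 9.24 (0.865) and Dcn was 73.8 in db/db 1 against 91.0 to 94.9 (0.835). mt-Nd4 was 4493 FPKM in db/db 4 and listed at 0 in the other db/db samples (gap 1 of the range). Slc1a4 was 0.130 FPKM in lean 2 and close to 0 in the other lean samples (gap 1 of the range).

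The fall of male-biased genes, taken as a set, was partial in db/db 1. For female-biased genes no such share was computed. Female animals among the db/db samples are excluded by the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, whose lowest summed FPKM in a db/db sample was 1.053 times the lean mean. Lean RNA mixed into db/db 1 is argued against by 14 other genes that fell at least 8-fold. In these db/db 1 held a median of 2.228% of the lean signal (quartiles 0.3372 and 4.842%). Over the 8 male-biased genes that fell, the median was 36.7% (quartiles 18.1 and 44.9%). Single genes went the other way: Egfr among the other genes was at 50.97%, and male-biased Hsd3b5 and Cyp7b1 were at 2.791% and 12.66%. The male-biased genes did not have to fall 8-fold, so the sets were not matched on the size of the fall. The shared reads of the Cyp2b, Sult2a and Mup families were not tested and stay open for single members. A hormonal change tied to the db/db genotype, and its variation between animals, may lie behind the pattern and was not tested.

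H2-K1, a class I histocompatibility gene, fell from 792.3 to 84.2 FPKM and Rpl21 from 190.5 to 0.917 FPKM in db/db (log2 fold changes -3.24 and -6.64). The test written first, of a change in the whole antigen presentation or ribosome program, did not decide: the medians were -0.2326 over 8 antigen presentation genes and -0.73 over 45 other Rpl genes, on either side of the bound set for it. Taken apart after these values were seen, each fall went beyond its group, since the lowest antigen presentation gene was at -0.7262 and the lowest other Rpl gene at -1.411. Among Rps genes, Rps18 and Rpsa also stood apart from the rest, at -2.862 and -2.604, less than Rpl21, and this was not explained. Sequence of another mouse background, aligned less well to the reference, may explain H2-K1: 3 of the 4 other polymorphic H2 genes tested were called (H2-Aa -2.05, H2-Ab1 -2.004, H2-Eb1 -1.26). The remaining one, H2-D1, a class I gene like H2-K1, was at -0.396 and not called (limma adjusted p = 0.0551). It was called with voom (log2 fold change -0.461, adjusted p = 0.0281). The 3 called genes are class II genes of antigen-presenting cells, and for these cells Cd74 was undecided at -0.7193 (SE 0.27, limma adjusted p = 0.0699). The background of the db/db mice is not given, so background and genotype stay confounded, and for Rpl21 no test of the background was run.

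Exact zeros of mitochondrial genes were found in db/db samples only. mt-Co1 was at 0 in all 4, while mt-Nd4, mt-Co3, mt-Nd3, mt-Nd4l and mt-Atp6, which share a locus in the table, were at 0 in db/db 1, 2 and 3 and above 0 in db/db 4. At the same locus mt-Atp8 was at 0 in db/db 1, 2 and 3 and close to 0 in all other samples, lean included (at most 0.000133 FPKM). A loss of all mitochondrial transcripts in db/db is argued against by mt-Nd1, mt-Nd2 and mt-Cytb, whose log2 fold changes went both ways (0.3529, 0.128 and -0.4366, mean 0.01479). Of these mt-Cytb was called lower (limma adjusted p = 0.0475), by far less than a fall to 0, and mt-Nd5 was called higher (log2 fold change 1.48). A failed estimate in the authors' processing is a candidate explanation, which the test chosen for it cannot decide. In that test, 0 genes outside the mitochondrial genome and Alb were at 0 in a sample and above 1000 estimated fragments in another of the same group. A loss of only some mitochondrial transcripts would give the same count. mt-Co1 and Alb, at 0 throughout a group, could not enter it. Why the zeros lie in db/db samples, and in db/db 4 for mt-Co1 alone, was not tested.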

How the results depend on the processing

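Voom on estimated fragments and leaving out mitochondrial genes or genes that share a locus were chosen after seeing the data. The number of genes that differed was 2892, and 2069 to 3179 over all alternatives (2182 to 2596 with 1 sample left out). Voom called 3179, of which 2652 were called in the same direction as with FPKM, and 866 genes differed by over 0.5 on the log2 scale between the 2 measures. Median-ratio rescaling and quantile normalization moved the share of higher genes among those called from 58.6% to 51.4% and 50.4%. The count of genes that differed at least 2-fold went from 637 to 1011 with a pseudocount of 0.1, which shrinks the change of low genes less, and to 1045 with voom, where the cause was not tested.

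Camera called 11 lists with any 1 sample left out, but 0 with an estimated correlation, 12 with fry and 13 without the filter. Fry lost the lists of cholesterol synthesis and of Kupffer cells, and gained those of gluconeogenesis and glycogen, of insulin and IGF signalling and of pericentral genes. Without the filter the lists of lymphocyte and pancreatic acinar markers were gained, and with a replicate block that of neutrophil markers, each as lower. Psmd14 had a log2 fold change of 0.46 to 0.64 with 1 sample left out (0.4627 to 0.6435), 0.4851 without db/db 2 and 0.4851 without db/db 4, where fewer samples remained and the call was lost. Mettl3 had -0.2912 with voom and lost its call, and the cause was not tested. Mettl3 is also 1 of the genes that share a locus, so it has no value in the alternative that leaves these out. The labels do not say whether the replicate numbers pair the samples. Correlations of same-numbered deviations were -0.22, 0.03, 0.11 and -0.01, and those of unlike numbers ran from -0.234 to 0.295. This gives no sign of pairing but cannot exclude it. A replicate block gave 2514 genes and 12 lists, the log2 fold changes of Psmd14, Mettl3 and Acss3 being 0.55, -0.63 and 3.21.

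Of the 2892 called genes, 5 changed sign with voom, 2 with quantile normalization and 1 with each row as its own gene. Among the named genes, sign reversals were seen in those that did not pass the threshold: Arg1 (-0.01394 with median-ratio rescaling, and -0.01492 to 0.09475 with 1 sample left out), Cyp2e1 (0.03912 with quantile normalization) and Hbb-bs (0.01783 with quantile normalization, and -0.2321 to 0.3899 with 1 sample left out), and the cause was not tested. Over the named genes other than the study genes, 1536 values under alternatives kept direction and side of the threshold, 51 lost a call, 6 gained one and 6 changed sign. The gains were Lepr and Slc27a5 with voom, Cyp2e1 with library weights and without db/db 1, and S100a9 with a replicate block and without lean 2. Depth limits the genes near 0.5 FPKM, and limma recovered 22.4% of simulated changes of 0.5 on the log2 scale.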

Other observations

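Of the tests in this part, that of the authors' scaling was chosen after the result was seen, and the pathways came from the table's own annotation and were examined after the data were seen. Among 274 pathways with at least 10 tested genes, branched-chain amino acid breakdown rose in db/db, with 30 of 46 genes higher and 1 lower (camera adjusted p = 7.99e-08; adjusted p = 0.374 with an estimated correlation). Propanoate metabolism had 19 of 28 genes higher and 0 lower (camera adjusted p = 1.03e-06; 0.374 with an estimated correlation), and the citrate cycle 16 of 28 higher and 2 lower (camera adjusted p = 0.00263; 0.42 with an estimated correlation). Complement and coagulation genes, mostly secreted by hepatocytes, had 4 of 62 higher and 20 lower, and spliceosome genes 0 of 122 higher and 27 lower (camera adjusted p = 7.05e-05 and 0.000155; 0.471 and 0.374 with an estimated correlation). Pathways share genes, so these counts overlap.

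The ribosome pathway had 84 of 127 genes lower and 2 higher (camera adjusted p = 3.4e-23; 0.471 with an estimated correlation). Of 77 ribosomal protein genes tested, 73 were lower in db/db and 0 higher, with a median log2 fold change of -0.73. A bias against short transcripts was argued against by 231 other genes matched on transcript length and mean level (median length 789 against 751 bases), whose median was -0.09832, with 44 lower and 45 higher. The authors' scaling between libraries was argued against too, since the median was -0.7864 under median-ratio rescaling and -0.6093 under quantile normalization. Voom (median -0.7606) took its library sizes from the authors' size factors, so it could not test their scaling. Lower ribosomal protein transcripts may thus be part of the db/db liver state, as a hypothesis found and tested on the same data; a difference in background strain, in the share of cell types and in reads shared with the many ribosomal pseudogenes stay open and were not tested.

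The 8 samples can be split into 4 and 4 in 35 ways. For the genes that differ, 1 of the 35 splits, the real one, gave as many genes (2892 against at most 1 in another split). The real split also stood alone for genes at least 2-fold apart (637 against at most 1). It did so too for genes higher (1694 against at most 1) and genes lower (1198 against at most 1). These counts are parts of 1 result, and 1 of 35 is the smallest share the splits can give. Every other split mixes the groups, which adds the group difference to the spread within each side and lowers its count. The splits therefore cannot exclude chance for these counts. For the gene lists, 4 of the 35 splits gave as many calls (11 in the real split and at most 11 in another; the other 3 each kept 3 samples of a group together, and so part of the real difference), so chance cannot be excluded for the number of lists. In the 18 splits that put 2 samples of each group on each side, at most 8 lists were called.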
